A study of Mus musculus with 6 samples.

How the data were processed

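Thymus RNA from 3 Rag2/pfp knockout and 3 wild-type mouse samples was measured on 1-colour Illumina MouseRef-8 version 2 expression arrays, 1 array per sample. Per the labels' protocols, column-purified total RNA was amplified into biotin-labelled cRNA, hybridised and scanned with an Illumina bead array reader. Samples were assigned to genotype and replicate from their titles. Age, sex, strain, the BeadChip position of each array and the cell composition of the samples are not given in the sources used here.

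The probe intensities, per the file headers and the values, were deposited by the authors on a linear scale and not normalized between arrays, and GenomeStudio 2011.1 is the software named in the submitters' processing notes. A detection p-value per probe and array was deposited by the authors beside each signal, per the file headers, and its smallest step of 0.00125 corresponds to about 798 negative control beads. A second deposited table holds log2 values processed by the authors, and its scale was found from the values: it differed from log2 signals quantile normalized between the 6 arrays by at most 0.00187. Every column of that table had a median of 7.48, it was not centred on 0, and each column runs in the direction of higher signal; the order of the authors' steps is not given in the sources used here.

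The intensities were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with background estimated from the detection p-values and an offset of 16. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were tested (14097 of 25697). Of all probes, 23978 carried 1 gene symbol, 0 carried several and 1719 had no gene named in the annotation used, and 23962 of the named probes matched the reference gene table by gene ID, 16 did not and 0 symbols changed. The 826 tested probes without a gene name were tested but not named (39 higher and 54 lower). Among 16593 genes on the array, 9849 had a tested probe, and a gene was represented by its tested probe with the highest mean over the 6 arrays. Of 249 called genes with more than 1 tested probe, 173 had another probe called in the same direction and 0 had one called in the opposite direction.

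Knockout and wild type were compared with limma (lmFit and eBayes) without a block. Benjamini-Hochberg adjustment ran over all 14097 tested probes before the probe of each gene was taken, with a threshold of 0.05. Each difference is given as knockout minus wild type on the log2 scale. The median difference over all genes was 0.01 and the median SE 0.23. A probe not above background on any array of a genotype has only a bound there. The bound sets the mean of the brighter genotype against the mean, over the arrays of the dimmer genotype, of the higher of the lowest detected signal and the probe's own signal, and this applied to 54 called genes that were higher and 60 that were lower. No expression difference sets 1 probe against another. Probe means were ranked only to choose the probe that represents a gene. The number of arrays limits the precision of every value.

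Before the data were examined, 34 gene lists (cell types of the thymus and of neighbouring tissue, T cell development, and cellular processes), the comparison, the thresholds, the rule for naming genes and the alternatives were fixed. Lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with fry. Genes shared with another list numbered 10 in the chemokine list, 5 in the apoptosis list and 4 or fewer in each of the others. The genes named were Rag2, Prf1 and the neighbouring Rag1, the 12 largest rises and 12 largest falls among genes past the threshold with 1 symbol and no overlap between genotypes, and per list up to 4 members past the threshold with the largest change and up to 2 not past it with the highest mean. Antigen receptor segments and predicted genes were passed over among the 12. Any gene outside this rule was chosen after its values were seen and is marked as such.

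The alternatives were median centring without the quantile step, no background correction, an offset of 50, the authors' processed log2 values, no detection filter, detection on all 6 arrays at 0.01, the replicate number as a block, a mean-variance trend with robust moderation, array weights, the mean of a gene's probes, the probe with the largest spread, a test against a 1.5-fold change, leaving out each array in turn, camera with an estimated correlation, and fry. A block by BeadChip could not be fitted because no header names the chip of an array. Leaving out replicate 2 of both genotypes and taking the level of heart, fat, Xist or neighbouring organ transcripts as a covariate were added after the data were examined. No column of sample values was left unused.

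The limma and camera steps were tested on simulated arrays for this comparison with 9849 genes, independent noise per probe and 50 genes changed at each size. With each probe's own residual SD, 26%, 58%, 90% and 88% of genes changed by 1, 2, 3 and 4 on the log2 scale were recovered with 5 false calls and 0 wrong signs, the list that was moved was called, and 0 of 33 other lists were. With the median residual SD for every probe, 84%, 100%, 100% and 100% were recovered with 2 false calls, and 1 of 33 other lists was called. The simulated noise leaves out the correlation between genes of these data, estimated at 0.91 in the mitosis list. These counts therefore do not measure false calls of genes or lists in the real arrays.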

Results

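Gene expression was measured in the thymus of Rag2/pfp knockout mice and wild-type mice. Rag2 encodes a subunit of the recombinase that joins antigen receptor gene segments in developing T and B cells. Pfp is an older name of Prf1, the gene of perforin, the pore-forming protein of cytotoxic lymphocytes. Total RNA from 3 knockout and 3 wild-type samples was hybridised to 1-colour Illumina MouseRef-8 version 2 bead arrays, 1 array per sample. The arrays are named here by genotype and replicate number (knockout 1 to 3 and wild type 1 to 3). The labels do not say whether the samples came from separate animals. Xist and the Y-linked gene Eif2s3y (values below) set knockout 3 and wild type 2 apart from the other arrays, so no genotype was sampled from a single animal only. The p-values measure the spread between these samples, which may be technical in part. Each array carried 25697 probes, and between 13729 (knockout 3) and 13878 (knockout 2) of them had a detection p under 0.05. The median signal per array ranged from 172 to 186 units. With 3 arrays per group, the number of arrays limits the precision of every value.

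The comparison asked how the thymus transcriptome of the double knockout differs from that of the wild type. The targeted genes were examined first. The Rag2 probe (ILMN_1245983) had a normalized log2 signal of 7.20 ± 0.61 (SD, n = 3) in the knockout and 8.71 ± 0.50 (SD, n = 3) in the wild type. The knockout arrays 1 to 3 read 6.98, 6.73 and 7.88, and the wild-type arrays read 9.17, 8.17 and 8.78. The difference of −1.51 (SE 0.39) did not pass the threshold in the limma fit (adjusted p = 0.0579), although the groups did not overlap. It passed without knockout 3 (−1.85, adjusted p = 0.0467) and without wild type 2 (−1.78, adjusted p = 0.0388). The brighter Prf1 probe (ILMN_2960700) read 9.62, 9.59 and 9.61 in the knockout and 10.46, 9.90 and 10.38 in the wild type, a difference of −0.64 (SE 0.19, adjusted p = 0.0866). That difference passed without wild type 2 (−0.81, adjusted p = 0.0270). The other Prf1 probe (ILMN_1228333) differed by 0.06 (SE 0.24, adjusted p = 0.896). Where these probes lie relative to the deleted parts of the genes is not given in the sources used here, so their signals do not check the genotype labels. Rag1, which lies next to Rag2 and encodes the other recombinase subunit, was lower in the knockout by −2.13 (SE 0.25, adjusted p = 0.00734). Its adjusted p was 0.0520 without knockout 1 and 0.0506 without wild type 3.

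The genes with the largest falls in the knockout included surface receptors of T cells, and those with the largest rises included Il2ra, the alpha chain of the interleukin-2 receptor. Of 9849 genes tested, 600 were higher and 549 were lower in the knockout at an adjusted p of 0.05, and 447 and 429 of these changed by at least 2-fold. All 1149 had no overlap between the groups. Non-overlapping groups were found for 34.2% of the tested genes, where chance gives 10% on average. Genes vary together across these arrays, so the share can depart from 10% without an effect of genotype. Cd8b1, the beta chain of the CD8 co-receptor, fell furthest, from 15.12 ± 0.15 to 7.80 ± 0.92 (SD, n = 3 each; adjusted p = 0.00141). Cd4 fell by 4.65 on the log2 scale. Cd5, a surface glycoprotein of T cells, fell by 5.40. Slpi (−5.22), a secreted protease inhibitor, and the cystine transporter gene Slc7a11 (−5.12) fell as well. Gpr162 (−4.27), the casein gene Csn2 (−4.24) and Prg2 (−4.13), which encodes an eosinophil granule protein, fell too. Cd4, Csn2 and Prg2 were above background on 1 of the 3 knockout arrays, and Cd5, Slc7a11 and Gpr162 on 2. A probe not above background on any array of a genotype has only a bound there, given as "at least N-fold" from the brighter group's mean and the lowest detected signal of each array in the dimmer group. By this bound Fcmr, a receptor for immunoglobulin M, was at least 27.6-fold lower. Ampd1 was at least 24.8-fold lower, Lrrc57 at least 20.0-fold lower and Cd79a at least 15.8-fold lower. In the other direction, Tmem87a was at least 20.5-fold higher in the knockout, and the glycosyltransferase gene B4galnt2 at least 6.58-fold higher. Tmem87a and Lrrc57, which had the lowest p-values of all genes, lie 70 and 75 tested genes from Rag2 on the same chromosome, and Prg2 and Dll4 (named below) lie 50 and 53 tested genes from it. Il2ra rose from 7.20 ± 0.39 to 10.99 ± 0.34 (SD, n = 3 each; adjusted p = 0.00226). Dtx1, a target gene of Notch signalling, rose by 3.07 (SE 0.15), and Nfe2, a transcription factor gene of the megakaryocyte and erythroid lineages, by 3.24 (SE 0.35). The other genes among the 12 largest rises were Khdc1c (3.87), Aox2 (3.50), Rab44 (3.39), Slc5a9 (3.32), Myl10 (3.23), Ppp1r27 (3.05) and Gper1 (2.92), of which Khdc1c and Aox2 were above background on 2 of the 3 wild-type arrays and Gper1 on 1. Of 162 genes named by the fixed rule here and below, 92 were called, and none of these changed sign in a fit that left out 1 array (36 of the 92 passed in all 6 such fits). Of these 92, 76 passed with no detection filter, and with covariates chosen after the data were seen 68 passed with the Xist level and 81 with the neighbouring organ level. The number of genes called was 161 without knockout 1, 518 without knockout 3, 180 without wild type 1 and 158 without wild type 3, and in the same order 161, 499, 177 and 158 of them were among the 1149. Without 1 of these 4 arrays Khdc1c reached an adjusted p of up to 0.0880, Gper1 of up to 0.0706 (not without knockout 3), Csn2 of up to 0.0737 (not without knockout 3), and Aox2 of up to 0.0600 (without knockout 1 or wild type 3).

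**Figure D1:**
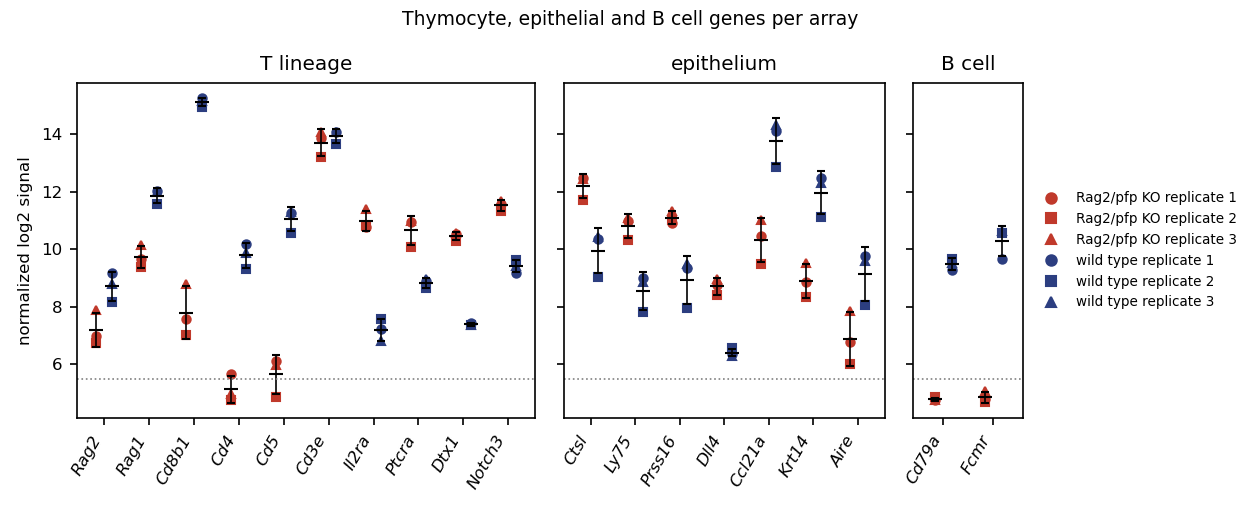
Normalized log2 signal of selected genes on each array (red, Rag2/pfp knockout; blue, wild type; marker shape gives the replicate number). Black bars show the mean and SD of 3 arrays and the dotted line the mean over arrays of the lowest detected signal, and Cd8b1, Cd4, Cd5 and Rag1 lie lower in the knockout and Il2ra, Ptcra, Dtx1 and Notch3 higher, while Cd3e has overlapping groups.

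Genes of CD4 CD8 double-positive thymocytes, the main population of a normal thymus, were lower in the knockout. Of 19 measured list members, 13 fell and none rose at the adjusted threshold (13 and 0 adjusted over the list alone, and 13 and 0 at an unadjusted p under 0.05). Besides Cd8b1 and Cd4 these included the costimulatory receptor Cd28 (−4.03, SE 0.33) and Slamf1 (−3.30, SE 0.22), while Arpp21 (−0.37, adjusted p = 0.372) and Aqp11 (−0.15, adjusted p = 0.806) did not pass. The only Cd8a probe was not above background on any array. Of 22 genes of single-positive and mature T cells, 11 fell and none rose (11 and 1 adjusted over the list alone, 13 and 1 at an unadjusted p under 0.05). Cd69 (−3.97), an activation marker, H2-Q2 (−3.64), Gimap7 (−2.82) and the chemokine receptor gene Ccr7 (−2.58) fell (H2-Q2 and Ccr7 were above background on 2 of the 3 knockout arrays), whereas Klf2 differed by 0.31 (adjusted p = 0.747) and Stat4 by 0.16 (adjusted p = 0.836). Of 17 genes of positive selection and the T cell receptor response, 5 fell and Socs3 rose (7 and 1 adjusted over the list alone). Socs3, a feedback inhibitor of cytokine signalling, changed by 0.85 and passed only without knockout 2 or wild type 2 when 1 array was left out (adjusted p otherwise up to 0.183). Cd5, Cd6 (−4.12), Itm2a (−3.15) and Egr2 (−3.03) fell, and Egr1 differed by −2.30 (SE 0.65, adjusted p = 0.0738) and Dusp6 by −0.30 (adjusted p = 0.481). Of 22 genes of the T cell receptor complex and its proximal signalling, 8 fell and none rose (13 and 1 adjusted over the list alone, 14 and 1 at an unadjusted p under 0.05). The adhesion receptor gene Cd2 fell from a mean level of 11.29 to 7.29, and Sit1 (−3.85), the kinase gene Zap70 (−2.93) and Satb1 (−1.75) fell as well. Socs3, Cd3e, Ptcra, Aire and Cx3cl1 are named here outside the fixed rule, having been chosen after their values were seen. The CD3 chains did not pass, with differences of 0.74 for Cd3g (adjusted p = 0.109), −0.12 for Cd3d (adjusted p = 0.832) and −0.21 for Cd3e (adjusted p = 0.661). All 4 lists were lower by camera with its preset correlation, with adjusted p-values of 3.15e-09, 9.71e-05, 0.00128 and 3.81e-07 in the order given. None held with an estimated correlation (adjusted p = 0.714, 0.743, 0.714 and 0.743 with an estimated correlation). Without knockout 1, wild type 1 or wild type 3, the falls numbered 7, 8 and 7 in the double-positive list and 3, 3 and 3 in each of the other lists. Without knockout 3 they numbered 4, 3 and 4 in the mature, selection and receptor lists, and without knockout 2 they numbered 6 in the mature list. Gimap7 and Satb1 missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.107), Egr2 also without knockout 3 (up to 0.102), and Ccr7 without any single array but wild type 2 (up to 0.137).

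Genes of double-negative thymocytes and early T cells, the stages before CD4 and CD8 appear, were higher. Of 18 measured members, 8 rose and none fell (9 and 0 adjusted over the list alone, 9 and 2 at an unadjusted p under 0.05). Besides Il2ra and Dtx1 the rises included Hes1 (2.46, SE 0.24) and Notch3 (2.12, SE 0.19), which belong to the Notch pathway, and Ptcra (1.83), the invariant chain of the pre-T cell receptor. Cd44 differed by −0.85 (adjusted p = 0.154) and Lmo2 by 0.09 (adjusted p = 0.932). The list was higher by camera (adjusted p = 0.000259), and adjusted p = 0.714 with an estimated correlation. The rises numbered 5 without knockout 1, 5 without wild type 1 and 4 without wild type 3, and Ptcra missed the threshold in these 3 fits (adjusted p up to 0.0729). Among 12 genes of V(D)J recombination and end joining, Rag1, Hmgb2 (−1.32) and Lig4 (−0.92) fell and Poll (1.05) rose (4 and 1 adjusted over the list alone). Dntt, the polymerase that adds nucleotides at receptor joints, differed by −0.23 (adjusted p = 0.603), and Xrcc6 by −0.39 (adjusted p = 0.361). That list did not pass (adjusted p = 0.206), and Hmgb2, Lig4 and Poll missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.152). Hmgb2 also missed it without knockout 3 or wild type 2, and Lig4 without knockout 2 or knockout 3.

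Cell division genes were lower in the knockout. Of 21 mitosis genes, 16 fell and none rose (20 and 0 adjusted over the list alone, 20 and 0 at an unadjusted p under 0.05), including the spindle motor gene Kif11 (−2.09, SE 0.20), Cdc25c (−1.96, SE 0.36), Birc5 (−1.85, SE 0.31) and Kif22 (−1.57, SE 0.30). Prc1 (−1.11, adjusted p = 0.0580) and Kif23 (−0.95, adjusted p = 0.107) did not pass. Of 26 DNA replication genes, 7 fell and none rose (15 and 0 adjusted over the list alone, 18 and 0 at an unadjusted p under 0.05). The ribonucleotide reductase gene Rrm2 (from a mean level of 10.80 to 8.80), Cdc45 (−1.42), Ccne1 (−1.42, above background on 2 of the 3 knockout arrays) and Ccne2 (−1.34) fell, while the helicase subunit genes Mcm4 (−0.35, adjusted p = 0.326) and Mcm5 (−0.80, adjusted p = 0.115) did not pass. Both lists were lower by camera (adjusted p = 9.76e-11 and 1.49e-07), and adjusted p = 0.743 and 0.743 with an estimated correlation. Without knockout 1, wild type 1 or wild type 3, limma called 1 mitosis gene in each case and no replication gene, and 20, 19 and 19 mitosis genes and 15, 9 and 12 replication genes were lower at an unadjusted p under 0.05. The replication calls numbered 4 without knockout 2 and 3 without wild type 2. Except for Kif11, the genes named here as having fallen missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.129), and Ccne2 also without knockout 3 or wild type 2.

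Genes of the cortical thymic epithelium, the stroma that supports early thymocytes, were higher, while genes of the medullary epithelium were lower. Of 17 cortical genes, 14 rose and none fell (16 and 0 adjusted over the list alone, 16 and 0 at an unadjusted p under 0.05). The Notch ligand Dll4 rose by 2.30 (SE 0.19), the protease gene Ctsl by 2.25 (SE 0.43), Ly75 by 2.24 (SE 0.38) and Pax1 by 2.23 (SE 0.29). Krt8 (1.39, adjusted p = 0.0590) and Tmprss2 (1.54, adjusted p = 0.135) did not pass. Of 19 medullary genes, 5 fell and none rose (9 and 0 adjusted over the list alone, 10 and 1 at an unadjusted p under 0.05). Krt14 fell by 3.06, and probes named for Ccl21a, Ccl21b and Ccl21c, near-identical chemokine genes whose probes may not tell them apart, fell (−3.43, −3.48 and −3.48). Aire, the regulator of peripheral antigen expression, differed by −2.25 (SE 0.62, adjusted p = 0.0712) and passed without wild type 2 (adjusted p = 0.0311). Krt17 differed by 0.09 (adjusted p = 0.908) and Trp63 by 1.25 (adjusted p = 0.167). Of 6 genes of peripheral tissue antigens, 3 fell and none rose (4 and 0 adjusted over the list alone, 4 and 0 at an unadjusted p under 0.05). These were Csn2, Fabp9 (at least 4.41-fold lower) and Pyy (at least 2.28-fold lower), whereas Apoa1 (at least 2.15-fold lower, adjusted p = 0.0550) and Wfdc12 (1.04, adjusted p = 0.480, above background on 2 of the 3 wild-type arrays) did not pass. The cortical list was higher by camera (adjusted p = 7.57e-11), and the medullary (adjusted p = 0.000236) and antigen lists (adjusted p = 0.0145) were lower. With an estimated correlation, these became adjusted p = 0.714, 0.743 and 0.743 with an estimated correlation. With the level of neighbouring organ genes (below) as a covariate, a choice made after the data were seen, the medullary mean difference was −0.65 in place of −1.46 (camera, adjusted p = 0.0188), and the antigen list did not pass (adjusted p = 0.0689). The cortical rises numbered 1 without knockout 1, 7 without knockout 3, 3 without wild type 1 and 2 without wild type 3, and 15 to 17 of the 17 genes were higher at an unadjusted p under 0.05 without any single array. Without knockout 1, wild type 1 or wild type 3, limma called no medullary and no antigen gene, and 9 medullary and 4 antigen genes were lower at an unadjusted p under 0.05 in each case. Without wild type 2 there were 9 medullary falls, and without knockout 2 or knockout 3 there was 1 antigen fall in each case. Dll4, which lies 53 tested genes from Rag2, passed without any single array. The other genes named here as changed missed the threshold without knockout 1 or wild type 3 (adjusted p up to 0.165), and all but Pax1 without wild type 1. Ctsl and Ly75 also missed it without knockout 3, and Fabp9 and Pyy without knockout 2 or 3.

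**Figure D2:**
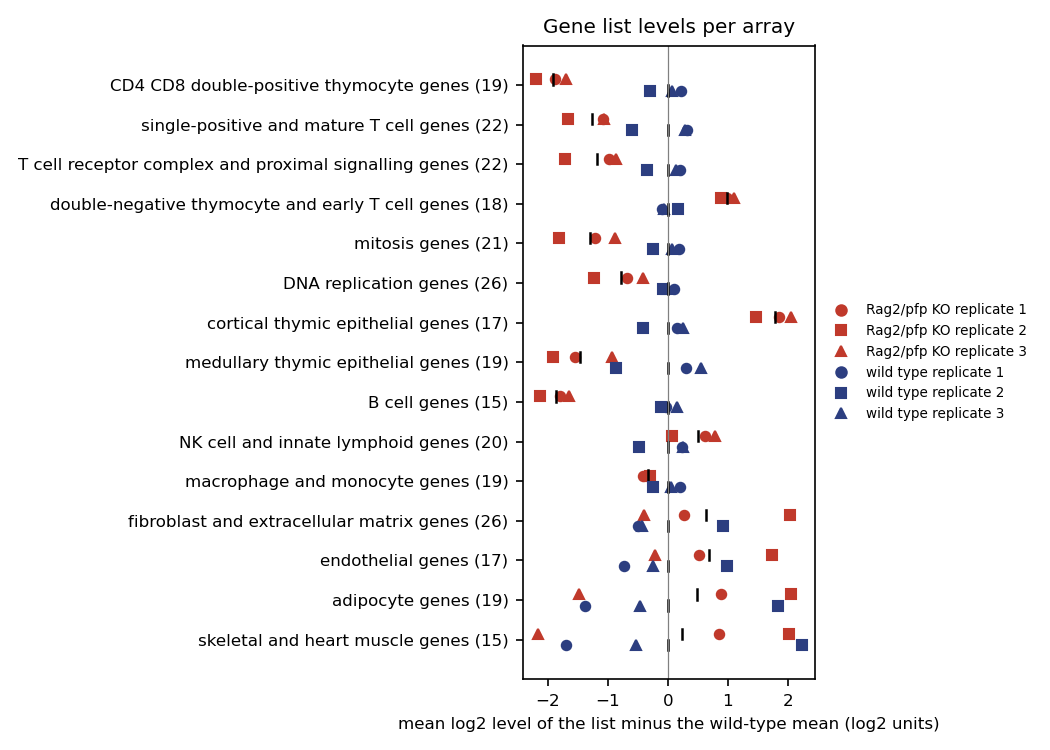
Mean normalized log2 level of 15 gene lists on each array, minus the wild-type mean of the same list (red, Rag2/pfp knockout; blue, wild type; marker shape gives the replicate number; black ticks, means of 3 arrays; number of measured genes in brackets). The double-positive, mitosis and B cell lists lie lower in all knockout arrays and the cortical epithelial list higher, while the fibroblast, endothelial, adipocyte and muscle lists have overlapping groups and are highest on both replicate 2 arrays.

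B cell genes were lower in the knockout. Of 15 measured, 8 fell and none rose (10 and 0 adjusted over the list alone, 11 and 0 at an unadjusted p under 0.05), among them Fcmr, Cd79a, which encodes a signalling chain of the B cell receptor, Pou2af1 (−3.50, SE 0.23) and Tnfrsf13c (at least 4.81-fold lower). Cd79b (−0.54, adjusted p = 0.212) and Blk (−0.16, adjusted p = 0.877) did not pass. The list was lower by camera (adjusted p = 4.61e-08), and adjusted p = 0.714 with an estimated correlation. The falls numbered 5 without knockout 1 and 5 without wild type 3. Among 20 NK cell and innate lymphoid genes, Klrg1 (2.00, above background on 1 of the 3 wild-type arrays), Xcl1 (1.43) and Rora (1.01) rose and none fell (3 and 0 adjusted over the list alone, 6 and 1 at an unadjusted p under 0.05). Nkg7 differed by 1.60 (SE 0.51, adjusted p = 0.102) and Ctsw by −0.35 (adjusted p = 0.655), and the list did not pass (adjusted p = 0.0657). It passed without knockout 2, wild type 1 or wild type 3 (adjusted p = 0.00985, 0.0136 and 0.0109), with no detection filter (0.0259), and with the heart, fat or neighbouring organ level as a covariate (0.0370, 0.0202 and 0.000186). Klrg1, Xcl1 and Rora missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.162). Klrg1 also missed it without knockout 3, and Xcl1 without knockout 3 or wild type 2. Of 19 macrophage and monocyte genes, Trem2 (−1.42), Lyz2 (−0.97) and Lyz1 (−0.77) fell and none rose (4 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05), while Vcam1 (0.52, adjusted p = 0.410) and Apoe (−0.27, adjusted p = 0.514) did not pass. Lyz1 had 3 tested probes and Lyz2 had 2, and no other probe of either gene was called. The macrophage list was lower by camera (adjusted p = 0.0145), and adjusted p = 0.743 with an estimated correlation. Without wild type 1 its adjusted p was 0.0553, with the neighbouring organ level as a covariate it was 0.0952, and its 3 genes each kept their call only without wild type 2 (adjusted p otherwise up to 0.179).

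Of 7 genes of neighbouring organs, Fcer2a, a receptor of B cells and follicular dendritic cells, and Tg, the thyroglobulin gene, fell (at least 2.48-fold and 1.49-fold lower). Ager (−1.23, adjusted p = 0.0825) and Cxcl13 (−1.26, adjusted p = 0.170) did not pass. The list was lower by camera (adjusted p = 0.0130), and adjusted p = 0.743 with an estimated correlation. No member rose (3 and 0 adjusted over the list alone, 4 and 0 at an unadjusted p under 0.05). Fcer2a and Tg both missed the threshold without knockout 1, knockout 3, wild type 1 or wild type 3 (adjusted p up to 0.0986), and 3 genes were lower without wild type 2. Of 21 interferon response genes, the transcription factor gene Irf1 rose (0.76, SE 0.17) and none fell (0 and 0 adjusted over the list alone, 5 and 0 at an unadjusted p under 0.05), while Gbp2 (0.60, adjusted p = 0.0968) and Irgm1 (0.24, adjusted p = 0.406) did not pass. The list was higher by camera (adjusted p = 0.0452), and adjusted p = 0.878 with an estimated correlation. Its adjusted p was 0.573 without knockout 2, 0.247 without wild type 2 and 0.995 without both, and Irf1 kept its call only without knockout 2 (adjusted p otherwise up to 0.143).

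Transcripts of heart, fat and other organs, some of them chosen for mention after their values were seen, varied between arrays of the same genotype. Nppa, the atrial natriuretic peptide gene, read 12.29, 14.20 and 4.79 on knockout 1 to 3 and 6.17, 13.48 and 8.09 on wild type 1 to 3. Ucp1, the uncoupling protein of brown fat, read 13.62, 14.24 and 6.13 in the knockout and 8.88, 14.01 and 11.75 in the wild type. The parathyroid hormone gene Pth read 6.33, 4.51 and 10.50 in the knockout and 10.68, 4.81 and 8.32 in the wild type. The first principal component (57.2% of the variance) did not separate the genotypes. The lists of fibroblast (26 genes), endothelial (17 genes), adipocyte (19 genes) and erythroid genes (5 genes) held no called gene by limma and 1, 0, 0 and 0 at an unadjusted p under 0.05. Dcn (0.30), Acta2 (0.51), Aqp1 (0.80), Egfl7 (0.68), Lpl (1.08), Pnpla2 (0.64), Hba-a1 (0.31) and Tfrc (−0.40) had adjusted p-values from 0.372 to 0.810. In the muscle list Mylpf (−2.40) and Pvalb (at least 3.44-fold lower) fell and 0 of 15 genes rose (2 and 0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05), while Nppa (1.18, SE 2.88, adjusted p = 0.825) and Myl1 (0.53, SE 1.69, adjusted p = 0.869) did not pass. Mylpf and Pvalb missed the threshold without knockout 1, wild type 1 or wild type 3, and Pvalb also without knockout 2 or 3 (adjusted p up to 0.128). These 5 lists did not pass by camera (adjusted p = 0.0676, 0.105, 0.439, 0.933 and 0.693). The fibroblast, endothelial and adipocyte lists passed as higher without knockout 3 (adjusted p = 0.000599, 0.00308 and 0.00559) and without wild type 2 (0.00192, 0.00544 and 0.0139), and the fibroblast list also without knockout 1 (0.0246). With both replicate 2 arrays left out, a choice made after the heart and fat transcripts were seen, 2878 genes were called, of which 1130 were among the 1149. Knockout 1, which also had high heart and fat transcripts, stayed in that fit. In that fit 13 double-positive, 19 mitosis, 11 B cell and 9 medullary genes were lower, and 16 cortical and 11 double-negative genes were higher.

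**Figure D3:**
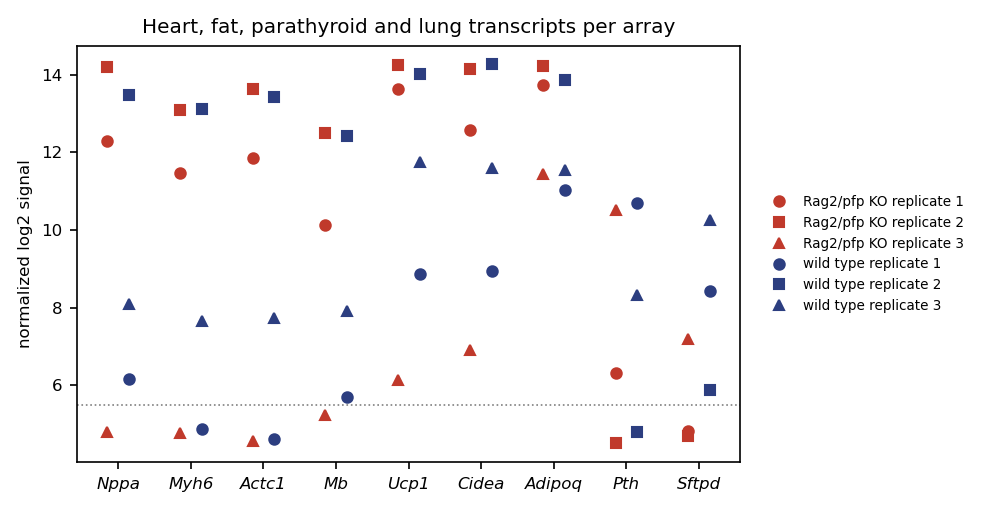
Normalized log2 signal on each array of heart (Nppa, Myh6, Actc1, Mb), fat (Ucp1, Cidea, Adipoq), parathyroid (Pth) and lung (Sftpd) transcripts (red, Rag2/pfp knockout; blue, wild type; marker shape gives the replicate number; dotted line, mean over arrays of the lowest detected signal). Heart and fat transcripts are highest on both replicate 2 arrays and Pth on knockout 3 and wild type 1.

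The remaining 13 lists did not pass by camera. Among genes of antigen presentation, Ciita (0.97) rose and H2-Ob (−1.96) fell in the class II list (12 genes, adjusted p = 0.156), and H2-T10 (−1.97) fell in the class I list (16 genes, adjusted p = 0.181). H2-Ab1 (0.71, adjusted p = 0.108), Cd74 (0.46, adjusted p = 0.305), B2m (0.08, adjusted p = 0.779) and H2-T23 (−0.01, adjusted p = 0.989) did not pass. The death receptor gene Fas (−2.19), Bcl2l1 (−1.63) and Bid (−0.99) fell in the apoptosis list (18 genes, adjusted p = 0.0556), and Mcl1 (−0.38) and Birc2 (−0.03) did not pass. In the chemokine list (21 genes, adjusted p = 0.741) Cxcl12 (1.83), Ccl25 (1.49), Xcl1 and Cx3cl1 (1.01) rose and Ccl21a and Ccl8 (−1.68) fell, while Ccl5 (0.36) and Cxcl16 (−0.34) did not pass. Cd83 (2.16) rose in the dendritic cell list (12 genes, adjusted p = 0.741), and Cst3 (0.07) and Ly6d (−0.47) did not pass. Cxcl12, Ccl25 and Cd83 are also members of the cortical epithelial list, and their rises are already counted there. The protease genes Mmp9 (1.96) and Cpa3 (1.92) rose in the neutrophil and mast cell list (15 genes, adjusted p = 0.933), where Ltf (−3.08, SE 1.37) and S100a8 (−2.35, SE 0.74) did not pass. Trp53inp1 (−1.17) fell in the p53 list (14 genes, adjusted p = 0.933), with Ccng1 at 0.54 and Mdm2 at −0.14. Jund (−0.89) fell in the immediate early and heat shock list (16 genes, adjusted p = 0.866), with Hspa8 at 0.24 and Zfp36 at −0.87. C6 (−1.96, above background on 2 of the 3 knockout arrays) fell in the complement list (10 genes, adjusted p = 0.439), with C1qb at −0.40 and C1qc at −0.28. Pfkp (−1.11) and Pdk1 (−0.63) fell in the glycolysis list (15 genes, adjusted p = 0.275), with Gapdh at −0.35 and Ldha at −0.43. Rpl22 (0.91) rose in the ribosomal list (22 genes, adjusted p = 0.866), with Rplp1 at −0.06 and Rps20 at 0.00. The oxidative phosphorylation list (32 genes, adjusted p = 0.703, Atp5b at 0.08 and Cox4i1 at −0.03) and the glucocorticoid response list (11 genes, adjusted p = 0.638, Mt1 at 0.38 and Tsc22d3 at −0.19) held no called gene by limma and 0 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, the 13 lists in the order given here had 1, 1, 0, 5, 1, 2, 1, 0, 0, 0, 0, 0 and 0 rises and 1, 1, 4, 3, 0, 0, 2, 0, 0, 2, 0, 0 and 0 falls. Median, mean and camera direction differed in sign for the dendritic, neutrophil and mast cell, erythroid, muscle, p53 and immediate early lists. The apoptosis list passed as lower without knockout 1, knockout 3 or wild type 2 (adjusted p = 0.0375, 0.0473 and 0.0140), with no detection filter (0.0316), without replicate 2 of both genotypes (0.0439) and with the Xist level as a covariate (0.0347). The class II list passed as higher without knockout 2 (0.0379) and with the fat or neighbouring organ level as a covariate (0.0441 and 0.00151), and the oxidative phosphorylation list as higher without knockout 3 or wild type 2 (0.0364 and 0.0191). Without wild type 2, limma called 5 lower apoptosis genes, 4 higher and 4 lower neutrophil and mast cell genes and 2 lower dendritic cell genes. Without knockout 1, wild type 1 or wild type 3 it called no chemokine gene (5, 5 and 5 higher and 4, 5 and 3 lower at an unadjusted p under 0.05), and Cx3cl1 passed only without knockout 2 (adjusted p otherwise up to 0.144). Of the changed genes of this paragraph, only Bcl2l1 passed without any single array. The highest adjusted p of the others without 1 array was 0.174, Pdk1 missed the threshold without each of the 6 arrays in turn, and Cd83, H2-T10 and Mmp9 missed the threshold only without knockout 1.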

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

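Of the tests reported in this part, the thresholds for showing untested probes, the test of a lower share of thymocytes, the tests of the B cell fall, leaving out replicate 2 of both genotypes, the heart and fat covariates, the tests of parathyroid, lung and lymph node tissue, the test of genes around Rag2 for another strain's segment, the comparison with other windows of the genome, and the tests of heart transcripts and of detection were chosen after the result was seen.

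Some probes were left out of the tests because fewer than 3 arrays detected them, and 6 of these reached a level of at least 8 on a knockout array, at least 2 above every wild-type array. Mfap4, a gene of elastic fibres, read 10.6 on knockout 2 against at most 6.11 in the wild type. On the same array Nox4 read 9.31 (at most 5.77 in the wild type), Lmod1 8.89 (at most 5.44) and Ccn5 8.54 (at most 5.35). Mup2 read 8.68 on knockout 1 (at most 5.37) and Serpinb3d 8.50 on knockout 3 (at most 5.48).

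Cortical epithelial genes had a mean difference of 1.79, medullary epithelial genes of −1.46 and B cell genes of −1.86. A lower share of thymocytes would raise the genes of every other cell type alike. The cortical mean lay 3.25, 3.65, 2.13, 1.16 and 1.11 above the medullary, B cell, macrophage, fibroblast and endothelial means. A permutation test over genes gave p = 1e-05 each, the smallest that 100000 permutations can give. Genes of a list are not independent, and this test leaves out the spread between arrays. It also tests a gap that had already been seen, so its p is not used as support. The 95% interval over arrays started at 2.51 for the medullary gap and ran from −2.32 to −1.41 for the B cell mean. This argues against a lower thymocyte share as the whole cause. The fibroblast and endothelial gaps overlapped between genotypes and are not used. Knockout 2 read 11.053, 11.129 and 10.798 for the cortical, fibroblast and endothelial levels, and wild type 1 read 9.741, 8.592 and 8.329. Heart or fat tissue is argued against as the whole cause of the B cell fall and of the gap between cortical and medullary means, since the gap was 3.22 with the heart level and 3.17 with the fat level as a covariate and the B cell mean −1.85 and −1.82 (3.42 and −1.78 without replicate 2 of both genotypes, which does not remove the tissue because knockout 1 also carries its transcripts). With the level of 7 neighbouring organ genes as a covariate the gap was 2.85 (95% interval over arrays 2.37 to 3.33) and the B cell mean −1.66 (−2.17 to −1.16). This argues against the level of these genes as the whole cause of either. It does not settle parathyroid or lung tissue, because the covariate also holds Fcer2a and Cxcl13. Within each genotype it was lowest on replicate 2 (5.33 and 6.34), where the heart level was highest (9.87 and 10.1). The medullary mean with the covariate was −0.65 (−1.36 to 0.06) and without it had an interval of −2.91 to −0.01. The covariate moved with the medullary level itself. It read 5.89, 5.33 and 7.30 on knockout 1 to 3 and 8.26, 6.34 and 8.03 on wild type 1 to 3. The medullary list read 8.20, 7.84 and 8.82 in the knockout and 10.05, 8.88 and 10.3 in the wild type. The adjustment therefore cannot separate organ tissue from a change in the medulla. Parathyroid, lung or lymph node tissue stays open for the medullary fall, without support from the smaller difference. The list behind the covariate was itself lower in the knockout, so the covariate can also take out part of a genotype difference. Whether the B cell transcripts of the wild-type samples came from the thymus or from lymph node tissue cannot be told. Cxcl13, which the chemokine list also holds, had a difference of −1.26 (−2.96 to 0.45), and Fcer2a is itself a B cell gene. Whole-tissue RNA also does not separate cell numbers from expression per cell.

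The genes with the lowest and second lowest p of 9843 genes placed in gene order, Tmem87a and Lrrc57, lie 70 and 75 tested genes from Rag2 on the same side, and 14 of the 200 tested genes nearest Rag2 (7%) were called at 4-fold or more, against 2.11% elsewhere (Fisher's exact test, one-sided p = 0.000134). Neighbouring genes are not independent, which makes the p too small. Of 5441 overlapping windows of 200 genes centred on other genes, none sharing a gene with the Rag2 window, 0 held 14 such genes (mean 2.10% of the window, SD 1.14%, highest 12 genes or 6%). Among 39 windows of 200 genes that do not overlap, however, the one holding Rag2 had 11 such genes and the highest of the others 12. Fixed windows can divide the genes near Rag2, and those beside it on chromosome 2 held 1 and 10. The 14 genes also include Rag1 and Dll4, members of the double-positive and cortical lists. The change in cell types as the source of the excess therefore stays open. A segment of another strain around the targeted allele may be a source, but at any fold 15% of these 200 genes were called against 11.6% elsewhere (Fisher's exact test, one-sided p = 0.0881), and around Prf1 13% were against 11.6% (p = 0.307), with 1% against 2.23% at 4-fold or more (p = 0.938). Sequence variants under single probes are also open: of 5 called genes with several probes, another probe moved the same way by at least 50% of the size in 3 (60%, exact interval 14.7 to 94.7%). A strain segment and probe variants cannot be told apart here, because the strains are not given in the sources used and the windows hold too few genes.

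Heart and fat transcripts were highest on replicate 2 of both genotypes, but knockout 1 was also high, with heart and fat means of 8.69 and 11.8 against 5.68 and 9.39 on knockout 3 (9.87 and 12.9 on knockout 2). The median over 15 heart and muscle genes exceeded the higher of the other arrays of its genotype by 1.67 on knockout 2 and by 3.59 on wild type 2. Neighbouring tissue in these samples stays open, because this excess restates the pattern and does not test its source. Array brightness or detection is argued against. The replicate 2 arrays detected at most 0.529% more probes than the higher of the other arrays of their genotype. Knockout 2 detected 13878 against 13805 and 13729, and wild type 2 detected 13834 against 13804 and 13798. Their median signals of 172 and 180 were not the highest of their genotype. Whether any such tissue entered at dissection was not tested, and no biological explanation was tested because it occurs in both genotypes.

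Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one, 1149 genes) gave as many called genes, and the highest of the others gave 133. With 10 splits the share cannot be under 0.05. At an unadjusted p under 0.05 in the limma fit, the split of knockout 1, knockout 2 and wild type 2 from the other arrays gave 2130 genes, and the real split 2815.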

How the results depend on the processing

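Leaving out replicate 2 of both genotypes and the heart, fat, Xist and neighbouring organ covariates were chosen after the result was seen. Over all alternatives, results for named genes were the same in direction and side of the threshold 3058 times, newly past it 145 times, no longer past it 280 times and reversed 5 times (Blk, not called here, +0.59 with array weights and +0.60 without replicate 2 of both genotypes, and 3 genes named below); for lists the numbers were 731, 41, 35 and 5. Without a stated reason, the cause was not tested. Leaving out each array gave 66 to 733 higher and 84 to 773 lower genes, 66 to 551 and 84 to 614 of them at 2-fold, 4 to 7 lists higher and 10 to 12 lower, Rag2 from −1.85 to −1.28 and Prf1 from −0.81 to −0.53. At 2-fold, 257 genes were higher and 265 lower with no background correction, and 268 and 279 with the authors' processed values, where uncorrected background compresses differences. Rag2 (−1.51) reached an adjusted p of 0.0498 with detection on all 6 arrays, where fewer genes are tested. With no detection filter, 533 genes were higher and 453 lower, the NK cell list was newly higher (adjusted p = 0.0259) and the apoptosis list newly lower (adjusted p = 0.0316), and 76 of the 92 named genes called here passed. Testing against 1.5-fold gave 88 higher and 114 lower genes, all of at least 2-fold, as this asks for larger changes.

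With the replicate block, 1223 genes were higher and 1163 lower, 5 lists were higher and Rag2 had an adjusted p of 0.0241. The interferon list was no longer called (adjusted p = 0.0899), and the NK cell, fibroblast and endothelial lists were newly called higher (adjusted p = 0.0233, 0.000608 and 0.00477). The numbers were not taken to pair the samples, because deviations of same-numbered arrays correlated at 0.09, 0.76 and 0.57 and knockout 3 correlated best with wild type 1 (0.74). The array weights did not converge (33.3 for knockout 1 against 0.139 for wild type 2). With them, 3668 genes were higher and 3723 lower, 1046 and 789 at 2-fold, 5 lists were higher (fibroblast, endothelial and adipocyte newly, interferon no longer, adjusted p = 0.695), Rag2 was −1.83 and Prf1 −0.76. With an estimated correlation, camera of limma called 0 lists higher and 0 lower (1 and 1 at an unadjusted p under 0.05). By fry of limma, 2 lists were higher (double-negative and cortical, adjusted p = 0.00804 and 0.0111) and 3 lower (double-positive, selection and B cell, adjusted p = 0.00804, 0.0143 and 0.00323). The other 9 lists were not called by fry: mature T cell, receptor complex and neighbouring organ (adjusted p = 0.0906 each), mitosis (0.0640), DNA replication (0.125), antigen (0.132), macrophage (0.153), medullary (0.176) and interferon (0.490). A block by BeadChip was not run.

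Without replicate 2 of both genotypes, 1500 genes were higher and 1378 lower (792 and 677 at 2-fold), with Rag2 at −1.55 (adjusted p = 0.0383) and Prf1 at −0.80 (adjusted p = 0.0137). The heart covariate gave 1378 and 1291 genes, 5 higher lists, Rag2 at −1.45 (adjusted p = 0.00143) and Prf1 at −0.62 (adjusted p = 0.0325). The fat covariate gave 1325 and 1216 genes, 5 higher lists, Rag2 at −1.36 (adjusted p = 0.00157) and Prf1 at −0.60 (adjusted p = 0.0373). The Xist covariate gave 372 and 292 genes, 276 of the latter at 2-fold, and the apoptosis list was newly lower (adjusted p = 0.0347). Of the 92 named genes called here, 68 passed with it. Those that did not (adjusted p up to 0.0884) were Gimap7, Ccr7, Hmgb2, Lig4, Xcl1, Rora, Trem2, Lyz2, Lyz1, H2-Ob, Ciita, Irf1, Ccne1, Ccne2, Cdc25c, Kif22, Bid, Trp53inp1, Jund, Ccl8, Ccl25, C6, Pdk1 and Rpl22. Newly called lists were endothelial (higher) and apoptosis (lower, adjusted p = 0.0439 each) without replicate 2 of both genotypes, NK cell, fibroblast and endothelial with the heart covariate (higher, adjusted p = 0.0370, 0.0192 and 0.00701), and NK cell, endothelial and MHC class II with the fat covariate (higher, adjusted p = 0.0202, 0.0242 and 0.0441). The interferon list was not called without replicate 2 of both genotypes (adjusted p = 0.995) or with the heart, fat or neighbouring organ covariate (adjusted p = 0.0743, 0.0747 and 0.115).

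The neighbouring organ covariate gave 1023 higher and 777 lower genes (722 and 547 at 2-fold), 6 higher and 17 lower lists and Rag2 at −0.79 (adjusted p = 0.0338), and 945 of the 1149 genes stayed called with 0 of opposite sign. Lists not called here reversed to −0.63 (fibroblast), −0.51 (endothelial), −1.80 (adipocyte), −0.55 (oxidative phosphorylation) and 0.26 (ribosomal), as did Myl1 (−2.90), Nppa (−4.59) and Pnpla2 (−1.36), all called. The macrophage (adjusted p = 0.0952) and antigen lists (adjusted p = 0.0689) were no longer called, and NK cell and MHC class I and II lists were newly higher and erythroid, muscle, immediate early, complement and glycolysis lists newly lower (adjusted p up to 0.0353). Signal over background limits genes near background: a probe above it on no array of a genotype has a bound in place of a difference, while a probe above it on 1 or 2 of the 3 arrays, such as Cd4, Csn2, Prg2 and Klrg1, has a difference that rests partly on background.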

Other observations

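All genes in this part were chosen after their values were seen, and no test of a hypothesis is reported here. Among called genes outside the lists, Hey1 (2.51, SE 0.21, adjusted p = 0.00379), a transcription factor gene of the Notch pathway, and the homeobox gene Six2 (2.68, SE 0.27, adjusted p = 0.00598) were higher in the knockout and passed without any single array. Nqo1 (2.41, adjusted p = 0.0120), Prokr2 (2.83, adjusted p = 0.0256) and the catalase gene Cat (2.23, adjusted p = 0.0357) were also higher. Nqo1 missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.0672), Prokr2 without any single array but wild type 2 (up to 0.106), and Cat without any but knockout 3 or wild type 2 (up to 0.136).

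Among lower genes, the cell cycle transcription factor gene E2f2 (−2.58, SE 0.26, adjusted p = 0.00602), Rasgrp1 (−2.22, SE 0.25, adjusted p = 0.00682), which links antigen receptors to Ras, and the chemokine receptor gene Cxcr5 (at least 5.02-fold lower, adjusted p = 0.00310) passed without any single array. Sh2d1a (−3.12, adjusted p = 0.0153) missed the threshold without knockout 1, wild type 1 or wild type 3 (adjusted p up to 0.0757), and Prkcb (−2.08, adjusted p = 0.00857) without knockout 1 or wild type 1 (up to 0.0520). Krtdap (at least 4.63-fold lower, adjusted p = 0.0241), Spink1 (at least 8.74-fold lower, adjusted p = 0.0251) and Insm1 (−2.70, adjusted p = 0.0391, above background on 1 of the 3 knockout arrays) passed only without wild type 2 when 1 array was left out (adjusted p otherwise up to 0.144). Gng13 (−2.66, adjusted p = 0.0197) missed the threshold without knockout 3, wild type 1 or wild type 3 (up to 0.0882). Cat and Rasgrp1 lie 10 and 36 tested genes from Rag2.

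Of the untested probes, 1880 were detected on 1 or 2 arrays and 23 of these reached a level of 8 or more on an array. The secretory gene Scgb1a1 of the airway read 13.2 on wild type 3 and 7.37 on wild type 1, and at most 5.47 on the other 4 arrays. Bpifb1 read 11.7 and Scgb3a1 9.07 on wild type 3. The mean level of 2 Xist probes, which mark an inactive X chromosome, was 5.03 on knockout 3 and 4.76 on wild type 2 and between 8.95 and 9.37 on the other 4 arrays. The Y-linked gene Eif2s3y read 9.47 on knockout 3 and 9.40 on wild type 2 and at most 4.95 on the others. Knockout 3 and wild type 2 thus had a male pattern and the other 4 arrays a female pattern, so both genotypes mix sexes.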
